A study of Mus musculus with 11 samples.

How the data were processed

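Single-cell RNA-seq libraries (10x Chromium, 3' end counting with unique molecular identifiers, UMIs) were made from brain cells of C57BL/6 mice at the peak of EAE and of naive CTL mice. The labels give 6 libraries of all brain cells (3 EAE, 3 CTL) and 5 of CD31-positive cells (2 EAE, 3 CTL), each assigned to 1 of 2 sequencing batches. Batch 1 held 2 EAE and 1 CTL library of the total fraction and 1 EAE and 1 CTL library of the CD31-positive fraction, and batch 2 the rest. No label ties a library to 1 animal, so p-values measure the spread between these libraries, which may be technical.

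Per the submitters' processing notes, reads were processed with Cell Ranger and Seurat and the builds GRCm38 and mm10 were used, with no versions given. The deposited expression tables, 1 per fraction, hold natural log values of corrected count plus 1, where the corrected count comes from SCTransform, a regression that adjusts each cell's UMI counts toward a common depth. Whether 1 model was fitted over a whole table or 1 per library, and which filters on cells and genes were used, is not given in the sources used here. Back-transformed values lay within 2.05e-11 of whole numbers in the total table (19505 genes, 26821 cells) and within 1.23e-11 in the CD31 table (17021 genes, 27920 cells). The annotation deposited by the authors gives for each cell the UMI count before SCTransform, the percent of UMIs from mitochondrial genes, the summed corrected counts (a score, equal to the sum of the back-transformed table in every cell) and the cell type. Cell types were taken from this annotation, which has 18 types in the total fraction and 5 endothelial classes in the CD31-positive fraction. Because SCTransform already moves cells toward equal depth, a real difference in RNA content between cells is partly removed from these values, and they are not raw counts, so no count model was fitted.

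Cells named EAE3 in the CD31 files were assigned to EAE replicate 2 of that fraction, the single CD31-positive EAE library of batch 2 in the labels. Depth is given as total UMIs per library and median UMIs per cell. No doublet caller was run, since raw counts were not used here. Instead, cells above 0 for at least 2 of 6 marker genes of leukocytes, glia and mural cells were left out as an alternative in the endothelial comparisons. These were 12 and 854 EAE cells and 7, 416 and 1242 CTL cells of the CD31-positive fraction, and 41, 61 and 90 EAE and 119, 62 and 47 CTL cells of the total fraction.

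For each library and cell type with at least 20 cells, corrected counts were summed over cells and scaled to 1000000, giving x in corrected counts per 1000000 (CPM). Genes with a mean x of at least 20 were tested on log2(x + 10) with limma (empirical Bayes with a mean-variance trend) with sequencing batch as a covariate. This left 2 residual degrees of freedom in the CD31-positive and 3 in the total fraction, and fewer where a type was missing in a library. Fold changes are on the log2(x + 10) scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Differences of response between the 5 endothelial classes were tested with the same model on the difference of log2 values of 2 classes of the same library, for 10 pairs. A total of 24 program lists and 18 marker lists were tested by counts of members past the threshold, over all genes and adjusted over the list alone, and by limma's competitive set test (camera) with a preset correlation of 0.01 and again with an estimated one. With an estimated correlation the test rests on the few residual degrees of freedom, so it can seldom call a list. A list not called that way is not thereby shown to be unchanged. Lists with fewer than 5 tested genes got counts only. Shares of cells were compared by an exact two-sided permutation test over libraries. The share test planned for the CD31-positive classes was left out, because genes that define the classes themselves differed between conditions, and so were the shares of microglia, macrophages and endothelial cells in the total fraction.

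The samples, comparisons, tests, gene lists and naming rule were set before the data were examined. Genes named were, in each endothelial comparison, the 10 with the largest rise and the 10 with the largest fall past the threshold with a mean of at least 50 CPM and every EAE library on the same side of every CTL library, plus up to 4 members of each program list by p. In other types and in classes the 5 largest in each direction were taken, plus up to 2 members of a list whose count is printed, and the same rule was applied to differences between classes. Ccl5, Vwf and Slc38a5 in the CD31-positive fraction, Vcam1, Cd14, Slc6a6 and Clu in the venous class, Gfap in astrocytes, and the genes given to show transcripts of other cell types were chosen after their values were seen. Some items that these rules select are not reported here. Gene positions are from GENCODE annotation of GRCm38, in which 27 of 27 genes looked up were found by symbol.

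Alternatives set beforehand were pseudocounts of 1 and 50, no filter on low values or a mean of 100, no scaling to 1000000, median-of-ratios scaling, the mean of the deposited natural log values, no batch covariate, the replicate number as a block, and equal numbers of cells per library. Further ones were the exclusion of cells with other-type genes, a minimum of 50 cells and leaving out each library in turn. Chosen after seeing the data were a common minimum of 3187 UMIs per cell, the highest of the CD31-positive libraries' lowest values, leaving out the interferon class, equal weight per class, and leaving out genes at 0 in every library of 1 batch. The fit was tested on simulated data with 200 changed genes. The simulated noise was normal, independent between genes and of equal spread in all libraries, so the rates below need not hold for the real libraries. For the CD31-positive fraction (6731 genes) it called 85.1%, 97.0% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, 3.61% of its calls were false, and 20 simulations with no change gave at most 3 calls. For the total fraction (6287 genes) these values were 49.3%, 100%, 98.5%, 3.51% and 1. Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.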

Results

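Experimental autoimmune encephalomyelitis (EAE), here induced by immunisation against a myelin protein, is a mouse model of autoimmune attack on the central nervous system. Single-cell RNA-seq compared brains of C57BL/6 mice at the peak of EAE with brains of naive mice (CTL), to ask how the brain endothelium, the cell layer that lines vessels and forms the blood-brain barrier, differs in disease. The 11 libraries came from 2 cell fractions, all brain cells (3 EAE and 3 CTL) and cells selected for the endothelial surface protein CD31 (2 EAE and 3 CTL), and were sequenced in 2 batches that each held both conditions.

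The table of the CD31-positive fraction held 27920 cells, all annotated by the authors as 1 of 5 endothelial classes. The EAE libraries held 3852 and 3320 cells with medians of 3774.5 and 4380.5 UMIs (molecules counted once each) per cell. The CTL libraries held 4457, 8949 and 7342 cells with medians of 3465, 3114 and 3713 UMIs, and the total per library ranged from 17366657 to 30930396 UMIs. The table of all brain cells held 26821 cells of 18 annotated types. Its EAE libraries held 4847, 5665 and 6581 cells with medians of 6414, 6073 and 7417 UMIs, against 5063, 2989 and 1676 cells with medians of 3699, 4116 and 3879.5 in CTL. The lowest UMI count of a cell was 3187 in EAE replicate 2 of the CD31-positive fraction and at most 1752 in every other library of that fraction.

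In endothelial cells of the CD31-positive fraction (7172 EAE cells in 2 libraries, 20748 CTL cells in 3), the genes with the largest rises in EAE included the secreted proteins Lcn2 and Lrg1, the chemokine-binding receptor Ackr1 and the class II invariant chain Cd74. Lcn2, a secreted iron-siderophore binding protein, rose from 6.77 ± 3.77 corrected counts per 1000000 (CPM) in CTL (SD, n = 3) to 1787 ± 559 in EAE (n = 2), a log2 fold change of 6.83 ± 0.092 (SE) on the log2(x + 10) scale used throughout. Ackr1, a venule receptor that binds chemokines without signalling, rose from 4.38 ± 2.48 to 1149 ± 486, a log2 fold change of 6.38 ± 0.12. Lrg1, a secreted glycoprotein, rose from 5.96 ± 3.61 to 531 ± 94.0. Cd74, the invariant chain of MHC class II, rose from 38.9 ± 37.4 to 949.9 ± 859.7, with a wide spread between the EAE libraries and within-batch log2 fold changes of 4.90 and 4.60. The log2 fold change was 4.45 ± 0.16 for Ifitm1, an interferon-induced membrane protein. It was 4.33 ± 0.28 for Cxcl9 and 4.01 ± 0.21 for Cxcl10, both ligands of CXCR3, a chemokine receptor of T cells, and 3.64 ± 0.13 for Ch25h, the enzyme that makes 25-hydroxycholesterol. Ubd, a ubiquitin-like protein induced by interferon and TNF, was listed at 0 in the CTL libraries and reached 128 ± 80.9 CPM in EAE, and H2-Aa, an MHC class II chain, rose by a log2 fold change of 3.42 ± 0.38.

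Among the genes that fell, Car4, a capillary carbonic anhydrase, went from 1822 ± 224 to 635 ± 93.7 CPM, a log2 fold change of -1.56 ± 0.13 with an adjusted p of 0.001 (limma). Ptn, the growth factor pleiotrophin, fell from 1591 ± 133 to 607 ± 61.3, Slc7a1, a transporter of cationic amino acids, from 392 ± 55.5 to 152 ± 18.5, and the intermediate filament gene Nes from 376 ± 102 to 115 ± 26.1. Log2 fold changes were -1.57 ± 0.15 for Nrep, -1.41 ± 0.095 for the secreted factor Ndnf, -1.37 ± 0.24 for the matrix protein Hmcn1, -1.34 ± 0.10 for the CXCL12 scavenger receptor Ackr3 and -1.24 ± 0.16 for Lrrc49. In the GRCm38 build, Lcn2 lies on the minus strand of chromosome 2 (32384633 to 32388252), Ackr1 on the minus strand of chromosome 1 (173331886 to 173333750) and Car4 on the plus strand of chromosome 11 (84957786 to 84966044), all annotated as protein-coding.

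Limma called 435 genes higher and 532 lower of 6731 tested, of which 118 and 34 changed by more than 2-fold, and all 967 had the same sign in both sequencing batches. This agreement is partly built in, since opposite differences in the 2 batches raise the residual spread and such genes are seldom called. With no scaling of libraries to a common total, the split was 798 higher and 514 lower. The counts rested on EAE replicate 2 and CTL replicate 3: without the former, 2 genes were higher and 0 lower, and without the latter, 163 and 68. Without the batch term 55 genes were higher and 7 lower.

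**Figure D1:**
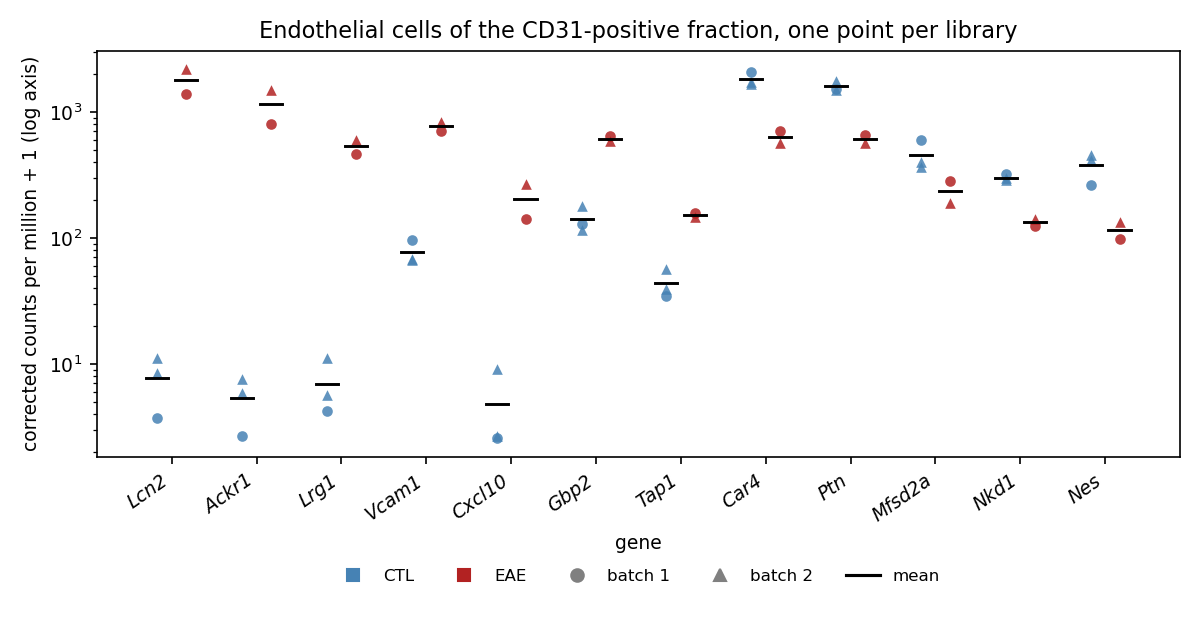
CPM plus 1 (log axis) of named genes in endothelial cells of the CD31-positive fraction, with 1 point per library, circles for batch 1, triangles for batch 2 and black lines at group means. The EAE libraries lie above every CTL library for Lcn2, Ackr1 and Lrg1 and below every CTL library for Car4 and Ptn.

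Most tested genes of antigen presentation and interferon response rose in these cells, beside leukocyte transcripts such as Ptprc, above 0 in 35.2% of the cells of EAE replicate 2. Of these lists, MHC class II had 4 tested genes and got counts only. With an estimated correlation the set test called none of the others. Of the 16 tested genes of MHC class I presentation all 16 rose, also when adjusted over the list alone. They included the peptide transporter Tap1 (42.6 ± 11.7 to 151 ± 7.65 CPM) and the class I genes H2-Q7, H2-T22 and H2-T23, with log2 fold changes of 2.84 ± 0.34, 1.48 ± 0.17 and 0.88 ± 0.092. All 4 tested MHC class II genes rose (4 adjusted over the list alone), among them H2-Ab1 at 3.08 ± 0.35 and H2-Eb1 at 3.13 ± 0.38. Of 22 type I interferon response genes 16 rose (18 adjusted over the list alone), with Ifi27l2a at 1.88 ± 0.16, Ifit3b at 1.63 ± 0.22 and Ifit2 at 1.54 ± 0.18. Of 15 interferon gamma response genes 13 rose (15 adjusted over the list alone), with the GTPase gene Gbp2 going from 140.0 ± 34.1 to 614 ± 40.7 CPM and the checkpoint ligand Cd274 changing by 1.76 ± 0.18. NF-kappaB target genes rose in 8 of 11 (8 adjusted over the list alone), with Bcl3 at 1.57 ± 0.085 and Relb at 1.14 ± 0.098.

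Genes for leukocyte adhesion and recruitment followed. Vcam1, a ligand of leukocyte integrins, rose from 75.9 ± 17.0 to 772 ± 88.7 CPM and Icam1 from 40.3 ± 19.6 to 248 ± 2.86. In all, 4 of 7 adhesion genes rose (4 adjusted over the list alone). Of 8 chemokines and cytokines 6 rose and 0 fell (7 rose and 1 fell adjusted over the list alone), with Ccl19 at 2.86 ± 0.18, Cxcl1 at 2.34 ± 0.13, the macrophage growth factor Csf1 at 1.68 ± 0.087 and Ccl5 at 2.09 ± 0.51. Of 17 acute phase and activation genes 14 rose and 1 fell (14 and 1 adjusted over the list alone), among them the uridine phosphorylase Upp1 at 2.87 ± 0.14 and von Willebrand factor Vwf at 1.81 ± 0.11. In glycolysis and hypoxia 6 of 10 rose (7 adjusted over the list alone), with the glycolytic activator Pfkfb3 at 1.61 ± 0.11 and Gapdh at 0.78 ± 0.12. Among 14 immediate-early genes 2 rose and 3 fell (3 and 3 adjusted over the list alone): Ier3 changed by 2.22 ± 0.12 and Junb by 1.27 ± 0.19, against -1.29 ± 0.16 for Dusp1 and -0.82 ± 0.13 for Jun.

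Part of the barrier genes fell. Of 18 blood-brain barrier transporters 10 fell and 1 rose (12 and 1 adjusted over the list alone). Those that fell included Mfsd2a, a lipid transporter that limits transcytosis (450.2 ± 125 to 235 ± 67.3 CPM), the transferrin receptor Tfrc (-1.09 ± 0.11) and the zinc transporter Slc39a10 (-0.82 ± 0.11), while the glutamine transporter Slc38a5 rose by 0.64 ± 0.098. Of 14 genes of the Wnt-dependent barrier program 6 fell (9 adjusted over the list alone), with Nkd1 at -1.13 ± 0.10, Axin2 at -0.71 ± 0.10 and Lef1 at -0.62 ± 0.11. Of 12 junction genes 4 fell (6 adjusted over the list alone), among them Ctnnb1, encoding beta-catenin, from 1065 ± 15.5 to 508 ± 139.6 CPM, Ocln by 0.63 ± 0.095 and Cdh5 by 0.58 ± 0.14. The caveolar genes Cav1 and Cav2 changed by -0.69 ± 0.10 and -0.71 ± 0.094, 2 of 7 in that list (2 adjusted over the list alone). Cavin1, Cavin2 and Cavin3 of this list were at 0 in every library of batch 2, which held older symbols for them. Only batch 1, with 1 library per condition, informs on these genes. In the angiogenesis list 5 of 10 fell and 1 rose (6 and 1 adjusted over the list alone), with the VEGF receptor Kdr at -1.03 ± 0.17, Tek at -0.74 ± 0.12 and the vasodilator peptide Adm at 1.81 ± 0.10.

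Lists fixed for other cell types also held genes that rose: 4 of 7 of the reactive astrocyte list (4 rose and 1 fell adjusted over the list alone), among them Lcn2, Cxcl10 and the ferroxidase Cp (1.09 ± 0.090), and 6 of 7 of an oligodendrocyte stress list (6 adjusted over the list alone), among them Cd74, Socs3 (1.48 ± 0.14) and class I genes. Of 6 genes of the microglial activation list 3 rose (3 adjusted over the list alone). The set test with an estimated correlation gave adjusted p of 0.305, 0.305 and 0.425 for these 3 lists. In basement membrane 1 of 10 rose, Fn1 at 0.52 ± 0.12 (1 adjusted over the list alone). In the cell cycle list 1 of 4 fell, Stmn1 at -0.55 ± 0.13 (1 adjusted over the list alone). None passed among 15 oxidative phosphorylation genes, 9 genes of cholesterol synthesis or 8 mitochondrial transcripts (4 of the last fell when adjusted over the list alone). The competitive set test called 11 lists higher and 5 lower with its preset correlation of 0.01, and none with an estimated correlation. The adjusted p was then 0.32 for MHC class I and both interferon lists, 0.305 for adhesion, chemokine, NF-kappaB and junction genes, 0.243 for acute phase genes, 0.32 for the Wnt and glycolysis lists and 0.436 for transporters. With 2 residual degrees of freedom, the smallest unadjusted p of the set test with an estimated correlation was 0.0164, for acute phase genes. Its lack of calls is therefore weak evidence against any list.

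Venous marker genes rose in 7 of 7 tested (7 adjusted over the list alone), while 4 of 7 capillary markers fell (6 adjusted over the list alone). The set test with an estimated correlation gave adjusted p of 0.243 and 0.305 for these lists. Lcn2, Lrg1, Vwf and Il1r1 are also in the acute phase list, Ackr1 in the adhesion list and Slc38a5 in the transporter list. The capillary markers Mfsd2a, Tfrc, Slc16a1 and Slc7a5 are transporter list members too, so these counts repeat genes counted above. Of 8 arterial markers 3 fell and 1 rose (4 and 1 adjusted over the list alone), and 3 of 10 general endothelial markers fell (6 fell and 1 rose adjusted over the list alone). Markers of other cells were present unevenly across libraries. The leukocyte gene Ptprc was above 0 in 35.2% of the cells of EAE replicate 2 and in 0.156% of those of EAE replicate 1, against 0.0224%, 2.06% and 3.02% in the CTL libraries. Cd74 was above 0 in 97.1% and 16.4% of EAE cells and in 0.269%, 18.2% and 10.4% of CTL cells, beside the rise of MHC class II and Ccl5 transcripts given above. The myeloid gene Lyz2 was above 0 in 52.0% and 3.35% of EAE cells and in 0.157%, 13.1% and 7.08% of CTL cells. Tyrobp, also a myeloid gene, was above 0 in 41.5% and 0.987% of EAE cells and in 0.112%, 9.45% and 23.4% of CTL cells.

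Endothelial cells of the total fraction (1143 EAE and 1352 CTL cells, 3 libraries each) showed the leading genes again. Lcn2 rose from 2.18 ± 2.06 to 1249.9 ± 381 CPM (n = 3 in each group), a log2 fold change of 6.63 ± 0.21. Ackr1 rose from 3.34 ± 5.55 to 764 ± 148, and Vcam1 from 38.3 ± 15.5 to 509 ± 88.2. Log2 fold changes were 4.32 ± 0.36 for Lrg1, 4.09 ± 0.50 for Cxcl10, and 3.41 ± 0.19 for Ch25h. They were 2.93 ± 0.23 for Ccl5, 2.79 ± 0.16 for Cd74 and 2.79 ± 0.17 for the secretoglobin Scgb3a1. Beside Ccl5 and Cd74 the same cells held more of other leukocyte transcripts: Lyz2 stood at 314 CPM in EAE against 89.3 in CTL, and Ptprc was above 0 in 6.69%, 3.33% and 7.97% of EAE cells and in 1.28%, 1.08% and 1.37% of CTL cells. The myeloid gene Tyrobp differed less, at 267 CPM in EAE against 178 in CTL. Its mean was not higher in EAE in the myeloid cells themselves, at 3610 against 3863 in microglia and 2806 against 3605 in macrophages. A smaller difference of Tyrobp, here and in the types below, therefore does not argue against more leukocyte RNA in EAE. Cxcl9 was listed at 0 in CTL and at 134 ± 75.6 in EAE. Nrep fell by 1.49 ± 0.13 on the log2 scale, Ptn from 1481 ± 92.1 to 719 ± 179 and Car4 from 1788 ± 167 to 814 ± 209. Nes, Ackr3, the ligand Gas6, the lipase Mgll, the protease Htra1 and the exchange factor Rasgrp3 fell too, with log2 fold changes from -1.09 to -0.82. Limma called 200 genes higher and 94 lower of 6287, all 294 with the same sign in both batches, an agreement that the fit partly builds in, as above. Without CTL replicate 1, 67 were higher and 13 lower, without EAE replicate 3, 86 and 53, and without the batch term 50 and 4. The number lower was 34, 51 and 56 without CTL replicate 2, CTL replicate 3 and EAE replicate 1.

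By list, with the number adjusted over the list alone in parentheses, 12 of 16 MHC class I genes rose (16), 5 of 5 class II genes (5), 8 of 15 interferon gamma genes (15) and 2 of 22 type I interferon genes (8). Likewise 6 of 9 NF-kappaB targets (7), 9 of 16 acute phase genes (14), 7 of 9 chemokines and cytokines (7) and 5 of 9 adhesion genes (7) rose. Examples were Tap1 at 1.45 ± 0.19, Gbp2 at 1.60 ± 0.17, Ifitm3 at 0.85 ± 0.19, Relb at 1.21 ± 0.15, Ccl19 at 2.29 ± 0.14 and Icam1 at 2.21 ± 0.20, and the selectin genes Sele and Selp were listed at 0 in CTL. Of 18 transporters 4 fell, Slc16a1 (-0.79 ± 0.14), Slc7a1 (-0.75 ± 0.13), Mfsd2a (-0.65 ± 0.12) and Slc22a8 (-0.57 ± 0.095), and adjusted over the list alone 8 fell and 3 rose. Nkd1 (-0.67 ± 0.13) was the single gene of 14 in the Wnt list and Ctnnb1 (-0.65 ± 0.085) of 12 in the junction list that fell (1 adjusted over the junction list alone). Venous markers rose in 6 of 8 (8 adjusted over the list alone), and 3 of 7 capillary markers fell (4). For these 2 lists the set test with an estimated correlation gave adjusted p of 0.138 and 0.215. The set test with its preset correlation called 12 lists higher and 3 lower. The lower ones were junction genes (adjusted p 0.0337), oxidative phosphorylation (0.00021) and mitochondrial transcripts (0.00139), while transporters (0.0875) and Wnt genes (0.0793) were not called. Without the batch term the last pair was called lower (0.0223 and 0.00718), and oxidative phosphorylation (0.0927) and mitochondrial transcripts (0.0598) were not called. With an estimated correlation it called none, with an adjusted p of 0.106 for class II, NF-kappaB, acute phase and chemokine genes.

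Across the 6207 genes tested in both fractions, 157 were higher in both (12.5 expected for independent lists), 67 lower in both (7.44 expected) and 1 opposite. Library names and batches are shared between the fractions, so the same mice may have given both, and the numbers for independent lists are then not what no change would give. The log2 fold changes of the 2 fractions correlated across genes, which are not independent replicates, with a Pearson r of 0.828 and a Spearman rho of 0.585.

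Lcn2, Ackr1 and Vcam1 are among the 10 genes that define the venous class, Cxcl10 among those of the interferon class and Clu among those of the arterial class, so their levels by class depend in part on how cells were assigned. The 10 genes that define the cap venous class include 4 haemoglobin genes (Hbb-bt, Hbb-bs, Hba-a1 and Hba-a2), and those of the cap arterial class include the immediate-early genes Fos, Egr1 and Nr4a1, so these classes may not stand for vessel segments alone. Lcn2 rose in each of the 5 endothelial classes of the CD31-positive fraction, and its level in EAE was highest in the venous class. It reached 97.0 CPM in the arterial class, 435 in capillary cells annotated as arterial-side (cap arterial), 899 in those annotated as venous-side (cap venous), 1485 in the class named interferon and 10739.9 ± 333 in the venous class, where CTL stood at 104 ± 78.0. Ackr1 reached 7060.4 ± 489 in venous cells, and its response in arterial cells minus that in cap venous cells was -3.14 ± 0.17 on the log2 scale (adjusted p 5.52e-05, limma on within-library differences). Such calls depended on single libraries: summed over the 10 pairs of classes they went from 2176 to 7 without CTL replicate 1. Vcam1 rose less in venous cells, where its CTL level was 801 CPM, than in the interferon class, where it was 49.0, with a difference of 2.52 ± 0.37 (adjusted p 0.0318). Cxcl9 rose by 6.55 ± 0.28 in the interferon class, by 5.35 ± 0.25 in venous and by 2.52 ± 0.34 in cap venous cells, and the cap venous response minus that of the interferon class was -4.03 ± 0.17. The monocyte receptor gene Cd14 reached 728 ± 279 CPM in venous cells, against 22.4 ± 23.5 in CTL, and its cap venous response minus the venous one was -3.36 ± 0.40. Cxcl10 reached 1289 ± 655 CPM in the interferon class, against 25.6 ± 36.2 in CTL.

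Car4 fell in all 5 classes, from 1653 ± 419 to 165 ± 49.0 in the venous class, a log2 fold change of -3.35 ± 0.14, which was larger than in cap venous cells by 1.93 ± 0.14 (adjusted p 4.02e-05). Nrep fell by 1.35 ± 0.16 in arterial and by 2.54 ± 0.16 in venous cells. Ptn fell by 2.57 ± 0.15 in venous cells and by 2.15 ± 0.14 in interferon cells, the latter a larger fall than in arterial cells by 1.44 ± 0.14. The taurine transporter Slc6a6 fell in venous cells by 2.38 ± 0.19, and its cap arterial response exceeded the venous one by 1.87 ± 0.15. Cyr61, a matricellular YAP target, fell in arterial cells (-1.82 ± 0.12), with an arterial response minus the cap arterial one of -1.41 ± 0.11. Clu, the chaperone clusterin, rose in venous cells by 2.73 ± 0.29, and the response of the interferon class minus the venous one was -2.84 ± 0.28.

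The barrier lists held more falls in the venous and interferon classes than in the arterial class, a contrast of counts that was not itself tested. They fell in this order: transporters 12, 13 and 2 of 18, Wnt genes 12, 9 and 2 of 14, and junction genes 8, 6 and 1 of 12. Adjusted over the list alone these were 13, 13 and 8, then 13, 14 and 5, then 9, 7 and 4. The set test with an estimated correlation gave adjusted p of 0.155 to 0.426 for these 3 lists in these 3 classes. Over all tested genes 1020 of 7116 fell in venous, 747 of 6612 in interferon and 49 of 6944 in arterial cells. The order of the classes is therefore not particular to the barrier lists. Genes that define the venous and interferon classes were called higher in EAE, so EAE and CTL cells of a class may not correspond. This limit holds for Car4, Ptn and the other contrasts by class above. Limma called 35 genes higher and 49 lower in arterial cells, 239 and 247 in cap arterial, 330 and 296 in cap venous, 533 and 747 in interferon and 458 and 1020 in venous cells. The share of calls that were higher depended on the scaling: in venous cells it was 31.0% and became 54.3% with median-of-ratios factors, which moved the median log2 fold change of all genes by 0.149. It moved from 41.6% to 58.6% in interferon, from 52.7% to 68.4% in cap venous and from 41.7% to 46.1% in arterial cells with no scaling, and to 60.9% in arterial cells with median-of-ratios factors. Without EAE replicate 2, the 5 classes gave 0, 4, 4, 8 and 7 calls in the same order. The arterial calls numbered 275, 19, 8 and 19 without CTL replicate 2, CTL replicate 1, CTL replicate 3 and EAE replicate 1.

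**Figure D2:**
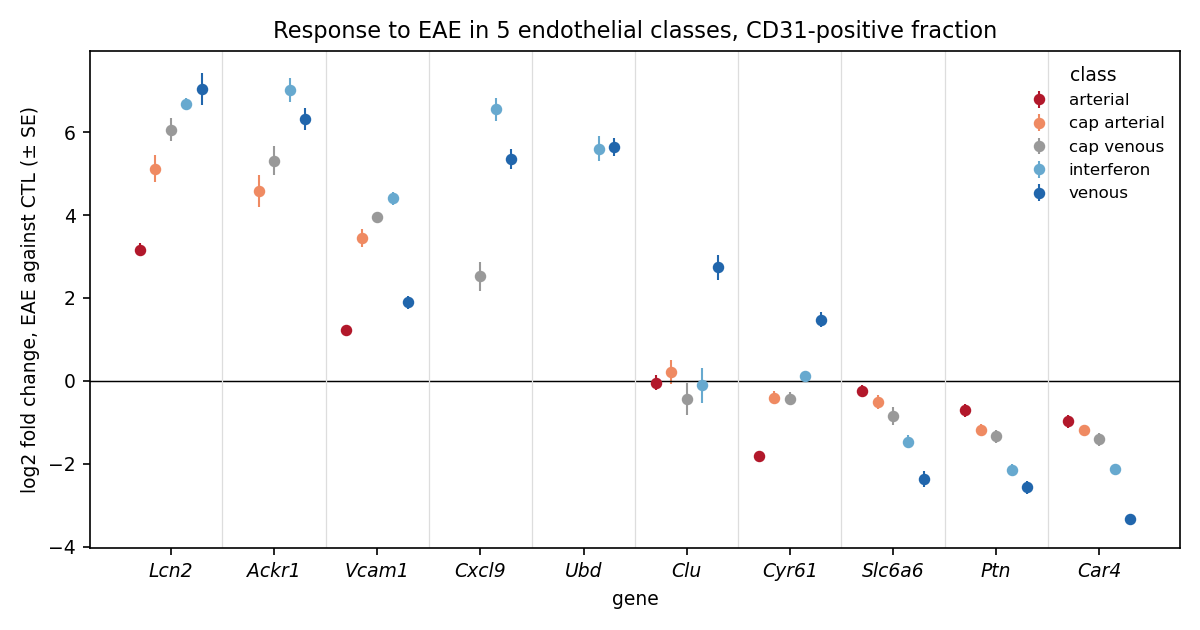
Log2 fold change of EAE against CTL (vertical axis, bars are SE) for named genes in the 5 endothelial classes of the CD31-positive fraction, with 1 colour per class. Lcn2 has a positive value in every class, and the Car4 value is lowest in the venous class at -3.35.

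Shares of the 5 classes were not compared, because genes that define the classes themselves differed between conditions: 7 of the 10 genes defining the venous class and 7 of the 10 defining the interferon class were called higher in EAE.

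Microglia, the resident macrophages of the brain (5366 EAE and 3496 CTL cells), carried MHC class II and chemokine transcripts in EAE and less of their resting signature. Cd74 rose from 185 ± 6.08 to 15220.0 ± 6995 CPM (SD, n = 3 each), a log2 fold change of 6.19 ± 0.31. Ccl5 rose from 12.6 ± 2.80 to 1470.1 ± 789, and H2-Aa, H2-Eb1 and Cxcl9 rose by 5.50 ± 0.36, 5.40 ± 0.32 and 5.40 ± 0.34. Lyz2, a transcript abundant in the cells annotated as macrophages, stood at 1182 ± 309 CPM in EAE microglia against 382 ± 36.4 in CTL. All 12 tested homeostatic microglial genes fell (12 adjusted over the list alone), among them the purinergic receptor P2ry12 from 3957 ± 253 to 903 ± 336 and P2ry13 by 1.64 ± 0.13. Fcrls, Hpgd, Fscn1 and Gpr34 changed by -3.07 ± 0.45, -2.48 ± 0.26, -2.34 ± 0.17 and -2.30 ± 0.22. Of 14 activation genes 13 rose and 1 fell (13 and 1 adjusted over the list alone), with the protease inhibitor Cst7 at 4.36 ± 0.22 and Cd52 at 2.03 ± 0.13. All 6 tested cell cycle genes rose (6 adjusted over the list alone), with the topoisomerase Top2a at 2.00 ± 0.16. With an estimated correlation the set test gave adjusted p of 0.335, 0.181 and 0.181 for these 3 lists. Limma called 972 genes higher and 1732 lower of 5819, and the share higher, 35.9%, became 50.9% with median-of-ratios factors, which moved the median log2 fold change of all genes by 0.107. The total of 2704 was 1456 without EAE replicate 3.

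Oligodendrocytes (1009 EAE and 1099 CTL cells), the myelin-forming cells, carried the interferon and MHC class I genes. Igtp, an interferon-induced GTPase, rose from 1.08 ± 1.02 to 691 ± 348 CPM, Serpina3n, a protease inhibitor, from 11.6 ± 6.95 to 1027 ± 405, and the class I gene H2-D1 from 113 ± 36.9 to 3167 ± 1298. Iigp1 and H2-T23 rose by 5.34 ± 0.34 and 5.21 ± 0.23. All 15 MHC class I, 18 type I interferon and 13 interferon gamma genes tested rose, as they did adjusted over the list alone, and the set test gave 0.0848 for each as the adjusted p with an estimated correlation. Wfdc18, Clu, 1700063D05Rik, Cst3 and Serpinb1a fell, with Wfdc18 at -1.22 ± 0.22 and Clu at -1.03 ± 0.21. In all 161 genes were higher and 38 lower of 6580. The total of 199 was 75 without EAE replicate 3 and 105 without CTL replicate 1. The leukocyte transcripts Lyz2 and Ccl5 stood at 230 and 91.8 CPM in EAE oligodendrocytes against 28.1 and 4.11 in CTL. The myeloid gene Tyrobp differed less, at 99.9 against 75.5.

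In astrocytes (658 EAE and 1977 CTL cells), Igtp rose from 9.02 ± 1.21 to 567 ± 458 CPM and Gbp2, Gm4951, Iigp1 and the immunoproteasome subunit Psmb9 by 3.56 ± 0.28, 3.53 ± 0.52, 3.53 ± 0.60 and 3.52 ± 0.31. The reactive astrocyte genes Gfap, Serpina3n and Cxcl10 rose by 2.54 ± 0.39, 2.42 ± 0.35 and 3.12 ± 0.43, 3 of 4 tested (4 adjusted over the list alone). Of 15 MHC class I, 17 type I interferon and 13 interferon gamma genes 14, 15 and 10 rose (15, 17 and 12 adjusted over the list alone), with an adjusted p of 0.0767 for each with an estimated correlation. Apln, Rorb, Fabp7, Serpinh1 and Dclk1 fell, Apln from 133 ± 18.0 to 62.1 ± 10.5. Limma called 84 genes higher and 5 lower of 6650, and it called 0 without EAE replicate 3, 45 without CTL replicate 2 or CTL replicate 3 and 303 without EAE replicate 1. The myeloid gene Lyz2 stood at 410 CPM in EAE astrocytes against 92.7 in CTL, and Ccl5 at 108 against 9.83. Tyrobp, also a myeloid gene, differed less, at 330 against 164.

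In ependymal cells (49 higher and 2 lower of 7600 genes), which line the ventricles, Lcn2 was listed at 0 in CTL and at 313 ± 257 CPM in EAE. There H2-Q4, Isg15, Ifit3 and the complement gene C4b rose by 3.69 ± 0.31, 3.58 ± 0.43, 3.54 ± 0.30 and 3.45 ± 0.23. The small heat shock protein gene Hspb1 and the chaperonin gene Cct7 fell by 1.86 ± 0.29 and 0.81 ± 0.15. The leukocyte transcripts Lyz2, Ccl5 and Cd74 stood at 281, 69.9 and 792 CPM in EAE ependymal cells against 44.5, 6.57 and 69.7 in CTL. In fibroblasts (27 higher and 0 lower of 7345, with 449 genes at an unadjusted p under 0.05 in limma), Lcn2, C3 and Cxcl9 were listed at 0 in CTL and at 579 ± 461, 361 ± 399.5 and 447 ± 451 CPM in EAE. Ccl19 and C1s1 rose by 4.02 ± 0.69 and 3.44 ± 0.33. The leukocyte transcripts Lyz2, Ccl5 and Cd74 stood at 198, 142 and 1197 CPM in EAE fibroblasts against 54.1, 18.1 and 339 in CTL. In choroid plexus cells (23 higher and 0 lower of 5146, with 307 at an unadjusted p under 0.05), Cd74, Ifi27l2a, Ifitm3, Gpx3 and H2-Aa rose by 2.86 ± 0.16, 2.72 ± 0.35, 2.35 ± 0.20, 2.25 ± 0.29 and 1.92 ± 0.22, beside the leukocyte transcripts Lyz2 at 112 CPM in EAE against 26.9 in CTL and Ccl5 at 66.1 against 2.83. In pericytes Ifitm3 was the single gene called, from 1140.5 ± 41.6 (n = 2) to 3232 ± 444 (n = 3), beside Lyz2, Ccl5 and Cd74 at 832, 123 and 974 in EAE against 161, 37.7 and 261 in CTL. The myeloid gene Tyrobp differed less. It stood at 190 CPM in EAE against 102 in CTL in ependymal cells and at 114 against 102 in fibroblasts. In choroid plexus cells it stood at 93.1 against 61.5, and in pericytes at 421 against 312. In neuroblasts and in cells annotated as unknown limma called 0 genes, with 229 and 539 at an unadjusted p under 0.05. The ependymal count was 20 without EAE replicate 3 and 32 without CTL replicate 1, and the choroid plexus count 6 without EAE replicate 3. The fibroblast count was 0 without EAE replicate 3 or CTL replicate 1, and 7 and 10 without CTL replicates 2 and 3. The pericyte call was lost without EAE replicate 3, CTL replicate 1 or CTL replicate 2, each left out alone.

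Cells annotated as macrophages (4356 EAE and 203 CTL cells) differed in their defining genes, 8 of 10 of which were lower in EAE. Ccl5 and Gpnmb stood at 3067 ± 825 and 1127 ± 275 CPM in EAE against 299.7 ± 513 and 57.9 ± 100.2 in CTL. The resident macrophage genes Lyve1 and Ccl24 stood at 10.1 ± 4.83 and 7.22 ± 0.947 against 582 ± 236 and 704 ± 376. Ly6i, Saa3 and Cfb were also among the largest rises, and Fcrls, Hpgd and Mgl2 among the largest falls. Limma called 567 genes higher and 568 lower of 6106, and it called 27 in all without CTL replicate 1, 2112 without CTL replicate 3, and 393, 424 and 224 without EAE replicates 1, 2 and 3. With no scaling 61.8% of the calls were higher.

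The mean level of the Cd74 transcript was higher in EAE in every type plotted for both conditions, going from 153 ± 22.7 to 1161 ± 409.5 CPM in astrocytes and from 42.2 ± 14.4 to 656 ± 153 in oligodendrocytes. It stood at 35139 in EAE cells of the dendritic cell class DCs.1 and at 790.5 in EAE T cells. The leukocyte chemokine Ccl5 was at 12974 CPM in EAE DCs.2 and 3050 in EAE T cells, against 169 in EAE endothelial cells and 91.8 in EAE oligodendrocytes.

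**Figure D3:**
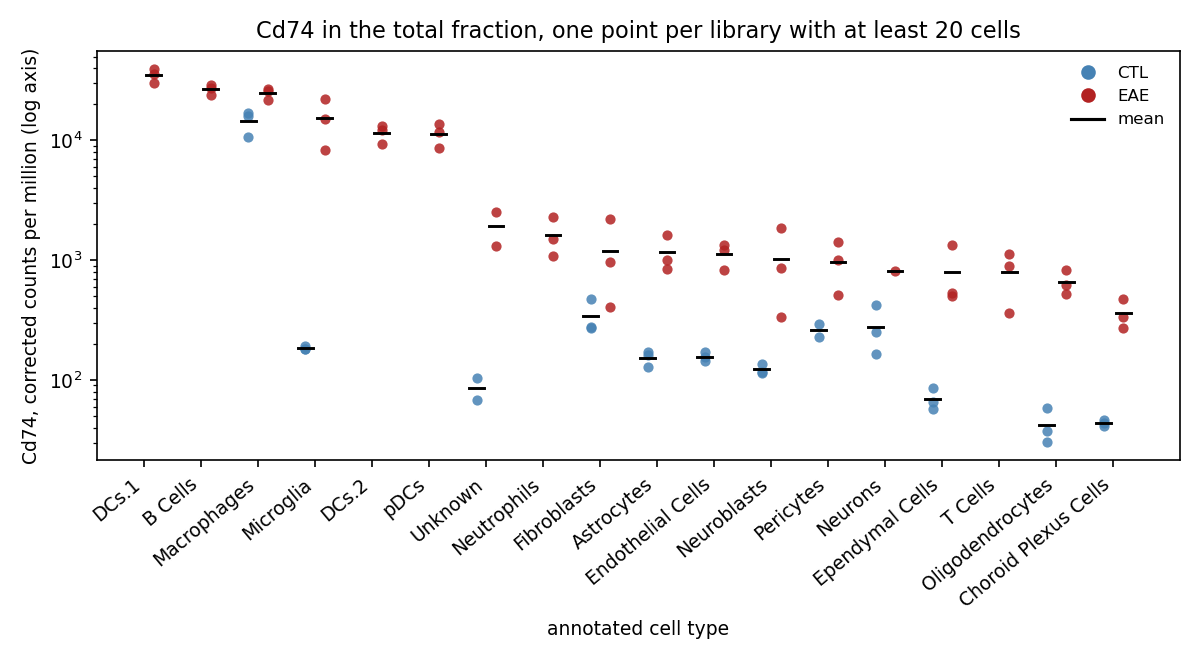
Cd74 in CPM (log axis) by annotated cell type of the total fraction, with 1 point per library of at least 20 cells and black lines at group means. In EAE, endothelial cells average 1129 CPM, microglia 15220 and DCs.1 35139.

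The 8 immune types, with microglia among them, together held 77.6% ± 3.45 of the cells in EAE (SD, n = 3) and 37.6% ± 4.03 in CTL (n = 3). T cells held 12.2% ± 2.22 against 0.381% ± 0.177, dendritic cells of the class DCs.1 2.90% ± 0.633 against 0.141% ± 0.0871, B cells 2.13% ± 1.39 against 0.0996% ± 0.0202 and neutrophils 1.34% ± 0.307 against 0.0599% ± 0.0403. The class DCs.2 held 1.59% ± 0.129 in EAE and 0 cells in CTL, and pDCs 0.671% ± 0.0586 against 0.0199% ± 0.0344. Astrocytes held 3.68% ± 1.66 against 22.2% ± 6.16, choroid plexus cells 2.19% ± 1.56 against 6.87% ± 2.06, ependymal cells 0.959% ± 0.144 against 3.08% ± 1.33, pericytes 0.529% ± 0.0506 against 1.44% ± 0.362 and neurons 0.223% ± 0.110 against 1.10% ± 0.860. In each of these the EAE and CTL libraries did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, with an adjusted p of 0.133 over the 16 shares compared. With leukocytes, here the immune types other than microglia, left out of the denominator, astrocytes held 6.94% ± 3.34 against 22.8% ± 6.21 and pericytes 0.977% ± 0.0393 against 1.48% ± 0.377, both still without overlap, while the choroid plexus, ependymal and neuron shares overlapped. Microglia (5366 EAE and 3496 CTL cells) stayed in that denominator. These shares therefore do not show whether astrocytes or pericytes differed among the non-immune cells alone. Oligodendrocytes (6.18% ± 3.96 against 9.04% ± 7.05), fibroblasts, neuroblasts and unknown cells overlapped between groups, with exact permutation p of 0.7, 0.2, 0.3 and 0.4, and the within-batch differences of unknown cells had opposite signs (0.247 and -1.01 percentage points). Shares of microglia, macrophages and endothelial cells were not compared, since 10, 8 and 4 of the 10 genes that define them differed between conditions.

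**Figure D4:**
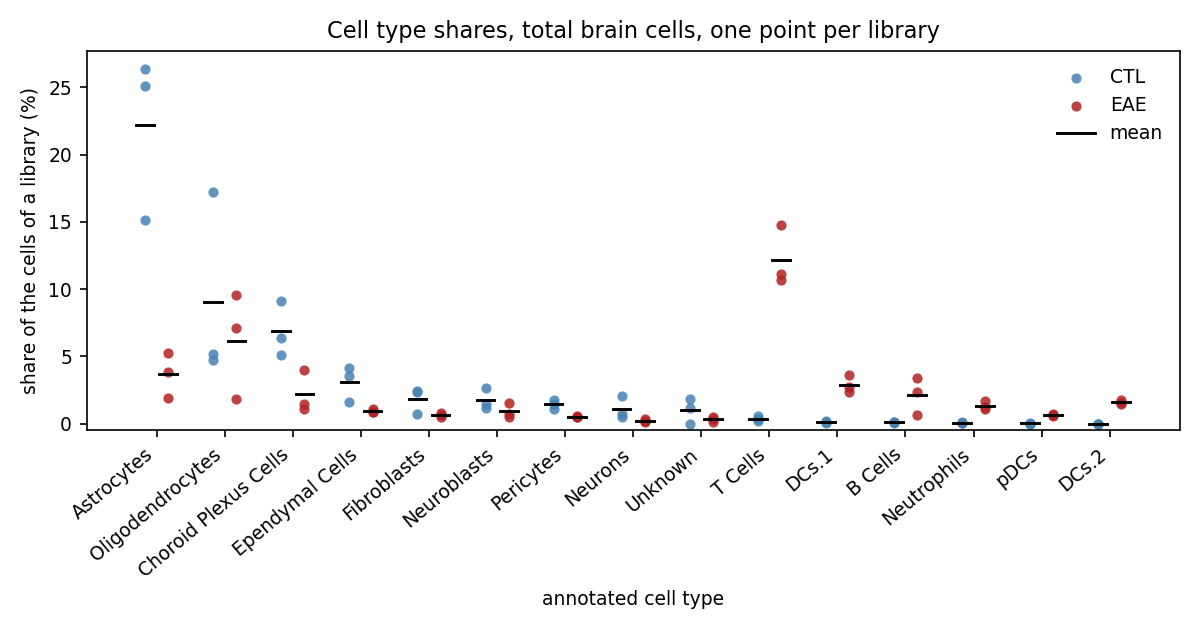
Share of the cells of each library (%) by annotated type in the total fraction, with 1 point per library and black lines at group means. T cells lie between 10.7% and 14.8% in EAE and below 1% in CTL, and astrocytes between 1.94% and 5.24% in EAE and between 15.1% and 26.4% in CTL.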

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

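The tests on a shift of cells between endothelial classes were chosen only after the result was seen.

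MHC class II transcripts were higher in EAE endothelial cells of both fractions, beside leukocyte transcripts such as Ptprc. The share of leukocyte RNA that the class II genes would need was compared with the share that the abundant genes of each of 8 immune types showed in the same cells. The lowest ratio was that of DCs.1, 1.12 in the total fraction (1.88% against 1.68%) and 0.877 in the CD31-positive fraction (1.82% against 2.08%), so RNA of that type may account for the class II level. The other types had ratios of at least 1.56 (macrophages) in the total and 1.86 (B cells) in the CD31-positive fraction. For microglia they were 3.79 and 9.04. Genes that endothelial cells raise themselves could be among the abundant ones, so the test cannot decide the source. In batch 1 of the CD31-positive fraction, with 1 library per condition, the lowest ratio was 2.75, against 0.800 in batch 2, and transcription of class II genes by the endothelial cells themselves stays open, untested. In the CD31-positive fraction, cells with 2 or more of the 6 other-type transcripts were excluded as the whole cause: without them the median log2 fold change of the 4 class II genes was 3.21, against 3.27, and all 4 stayed past the threshold. This covers only the cells left out, 12 of 3852 in EAE replicate 1 and 854 of 3320 in EAE replicate 2. Leukocyte RNA in cells with fewer of these transcripts stays open.

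All 7 tested venous marker genes were higher over all CD31-positive endothelial cells of EAE. For Ackr1, Lcn2 and Lrg1, the level over all endothelial cells of the lower EAE library was at least 2.07 times the highest level of any class in a CTL library, which no mixture of unchanged classes can give. For Il1r1, Nr2f2, Slc38a5 and Vwf, CTL class levels weighted by EAE class shares gave a median of 0.315 of the observed log2 fold change, and a shift of cells between classes and a change within classes cannot be told apart for these 4 genes, because the class annotation rests on genes that differ between conditions. A different minimum of UMIs per cell was excluded as the cause: with a common minimum 7 of 7 markers stayed past the threshold, with a median log2 fold change of 1.77, against 1.81. A response of the endothelial cells to EAE, which the design names, stays open as untested, beside the class shift for Il1r1, Nr2f2, Slc38a5 and Vwf alone.

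Some gene symbols were at 0 in every library of 1 sequencing batch and at a mean of at least 5 CPM in the other, 249 in batch 1 alone and 325 in batch 2 alone in the CD31-positive fraction and 300 and 310 in the total fraction. Of these, 96.8% and 32.0%, and 97.0% and 14.2%, were in the reference annotation, and the smaller of the differences, 64.8 percentage points, is consistent with 2 annotations with different symbols. Through listed synonyms, 182 and 207 pairs joined a current symbol in batch 1 to an older one in batch 2, and 0 pairs the reverse. Such symbols made up 170 of the genes tested in CD31-positive and 153 in total endothelial cells, with 0 calls among them in either, 2 in venous cells and 7 in microglia. Members of the program or marker lists among the symbols of 1 batch numbered 11 in the CD31-positive and 7 in the total fraction. Where these were tested, the list counts take in genes measured in 1 batch only. The batch 2 symbols of the CD31-positive fraction that were in the reference annotation include leukocyte genes such as Cd3e (a mean of 17.5 CPM in batch 2) and Ctla4 (13.2), for which leukocyte RNA in batch 2 stays open, untested. No biological explanation was tested.

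The EAE response differed between endothelial classes, by limma on within-library differences, for 469 genes between cap venous and venous cells, 417 between arterial and venous, 384 between arterial and interferon, and 348 between cap venous and interferon cells. It differed for 286 between cap arterial and venous, 104 between cap arterial and interferon, 90 between arterial and cap venous, 73 between interferon and venous and 5 between arterial and cap arterial cells. Between cap arterial and cap venous cells limma called 0 genes, with 791 at an unadjusted p under 0.05. Summed over the 10 pairs the calls were 2176, and 0, 7, 22 and 1397 without EAE replicate 2, CTL replicate 1, EAE replicate 1 and CTL replicate 2.

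With 3 libraries per group there are 10 splits of the 6 total-fraction libraries, too few for a share under 0.05. The real split called 294 genes in endothelial cells, 89 in astrocytes, 23 in choroid plexus cells, 51 in ependymal cells, 27 in fibroblasts and 199 in oligodendrocytes, and in each of these 2 of the 10 splits called as many. The other one was the split by sequencing batch, fitted without a batch term, with 1141, 1704, 1761, 419, 248 and 488 calls in the same order, which points to a structure of the samples. The real split without the batch term called 54, 45, 5, 26, 24 and 121. In macrophages and microglia 1 of the 10 splits, the real one, called as many as the 1135 and 2704 genes, with 158 and 216 for the split by batch. In neuroblasts the real split called 0, so that 10 of 10 called as many, and the batch split 393. In these 9 types none of the 8 remaining splits called more than 1 gene. Those splits mix EAE and CTL libraries within each group, so a difference between conditions adds to their residual spread. Few calls were therefore to be had from them, and they do not show what the real split would call without a change.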

How the results depend on the processing

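The common UMI minimum, the exclusion of the interferon class, equal weight per class and the exclusion of one-batch symbols were chosen only after the results were seen. Over 27 alternatives, 9346 values of 630 named genes and class differences kept their direction, and 1705 of them, 966 higher and 739 lower in EAE, were no longer past the threshold. All had passed the threshold in the main fit, the largest without overlap of EAE and CTL libraries, so reversals were unlikely from the start. Of the values no longer past the threshold, 1043 of 3356 came from leaving out 1 library, 280 of 630 from leaving out the batch term, 142 of 547 from having no low-value filter and 144 of 547 from the replicate block. Of the 20 genes with the largest changes in CD31-positive endothelium, 2 of the 18 with a value stayed past the threshold without EAE replicate 2, 18 without CTL replicate 3, 10 without the batch term, 17 with no low-value filter and 18 with the replicate block. In the total fraction 12 stayed without CTL replicate 1, 16 without EAE replicate 3, 19 without CTL replicate 2, 12 without the batch term and 10 with the replicate block. With equal numbers of cells per library, run for endothelial cells only, 20 of 20 stayed in each fraction, and what depth or cell numbers limit in the other types was not tested. In several runs that left out 1 library a condition had 1 library in a batch or in all, assumed to vary like the others. The alternatives for class shares of the CD31-positive fraction were not run, since those shares were not tested, and for unknown cells 1 run that left out a library could be fitted. Where no construction is named, the cause was not tested.

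Without the batch term the genes higher and lower numbered 55 and 7 in CD31-positive and 50 and 4 in total endothelium. The calls were 0 in arterial, 4 in cap arterial, 10 in cap venous, 301 in interferon and 473 in venous cells, 45 in astrocytes, 5 in choroid plexus, 26 in ependymal, 121 in oligodendrocytes, 0 in pericytes and 49 in unknown cells. With a filter of 100 CPM, which tests fewer genes, they were 166 and 295 in CD31-positive endothelium, 91 higher in the total fraction, 41, 292, 364, 684 and 651 in the 5 classes in the same order. They were 10 in choroid plexus, 24 in ependymal cells, 16 in fibroblasts, 507 in macrophages, 884 in microglia, 102 in oligodendrocytes and 8 in unknown cells. With no filter they were 214 and 84 in CD31-positive endothelium, 49 lower in the total fraction, 11 in arterial, 183 in cap arterial, 80 in cap venous cells, 23 in astrocytes, 0 in pericytes and 556 in unknown cells.

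With no scaling 798 genes were higher in CD31-positive endothelium and 23 were called in unknown cells, and with median-of-ratios factors 23 in arterial cells and 148 in astrocytes. A pseudocount of 1 gave 17 in fibroblasts, 0 in pericytes and 20 in unknown cells, and a pseudocount of 50 gave 4 in pericytes and 4780 differences between classes. The mean of natural log values gave 719 higher in CD31-positive and 50 lower in total endothelium. The common UMI minimum gave 1028 lower in CD31-positive endothelium, and leaving out one-batch symbols 218 in arterial cells, 44 in fibroblasts and 8 in pericytes. The set test called 11 lists higher and 5 lower in CD31-positive and 12 and 3 in total endothelium, and 0, 0, 0 and 0 with an estimated correlation. Without the batch term it called 11 and 5 in CD31-positive and 13 and 4 in total endothelium. With leukocytes left out of the denominator the oligodendrocyte share difference was 2.17 percentage points in place of -2.86, and the difference of logits was 0.0466 for unknown cells, whose share difference was -0.669 percentage points.

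In total endothelium the deviations of EAE and CTL libraries went with batch. They correlated at 0.788 for replicates 1 and 0.765 for replicates 3, each pair within 1 batch. The value was -0.693 for replicates 2, which lay in different batches, and 0.777 for EAE replicate 2 and CTL replicate 1 of the same batch. Because batch dominates these values, they cannot show whether libraries of the same number were paired within a batch. With the replicate block the genes higher and lower were 160 and 70 in CD31-positive and 57 and 4 in total endothelium, and the calls 4 in arterial, 110 in cap arterial, 168 in cap venous and 802 in interferon cells, 9 in choroid plexus, 111 in oligodendrocytes, 87 in pericytes and 148 in unknown cells.

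Leaving out 1 library at a time gave ranges of 2 to 382 higher and 0 to 432 lower in CD31-positive endothelium, and 67 to 230 and 13 to 107 in total endothelium. They were 0 to 275 in arterial, 4 to 481 in cap arterial, 4 to 789 in cap venous, 8 to 1058 in interferon and 7 to 1457 in venous cells, and 0 to 1604 for differences between classes. The lowest of each in the CD31-positive fraction came without EAE replicate 2. The ranges were 0 to 303 in astrocytes, 6 to 31 in choroid plexus, 20 to 66 in ependymal cells, 0 to 38 in fibroblasts, 27 to 2112 in macrophages, 1456 to 2632 in microglia, 0 to 3 in neuroblasts, 75 to 232 in oligodendrocytes, 0 to 48 in pericytes and 3 in unknown cells. The lowest came without EAE replicate 3 in astrocytes, choroid plexus, ependymal cells, microglia and oligodendrocytes and without CTL replicate 1 in macrophages. In fibroblasts it came without EAE replicate 3 and without CTL replicate 1 alike, and in pericytes without each of EAE replicate 3, CTL replicate 1 and CTL replicate 2. The oligodendrocyte share difference ranged from -5.01 to 1.21 percentage points and was positive without CTL replicate 1. The neuron share difference, -0.878 percentage points, was -0.385 without CTL replicate 3, a library with 2.09% neurons.

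Beyond those named in the report, the following runs without 1 library moved a count by over 1.5 times. Cap arterial cells gave 241 and 142 calls without CTL replicates 2 and 3, and cap venous cells 183 without CTL replicate 3. Interferon cells gave 785, 783 and 755 without CTL replicate 1, CTL replicate 3 and EAE replicate 1, venous cells 568 and 502 without CTL replicate 1 and EAE replicate 1, and pericytes 10 and 48 without EAE replicates 1 and 2.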

Other observations

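Microglia carried the interferon program as well as class II genes. All 16 tested MHC class I genes rose (16 adjusted over the list alone), with H2-Q7 at 4.57 ± 0.16 and H2-Q6 at 3.65 ± 0.15 on the log2 scale. Of 22 type I interferon genes 21 rose and 1 fell (21 and 1), with Ifi27l2a at 3.75 ± 0.13 and Ifit3 at 2.64 ± 0.12. Of 18 interferon gamma genes 17 rose (17), with the GTPase genes Iigp1 at 3.99 ± 0.13 and Gbp2 at 4.67 ± 0.16. All 7 chemokine and cytokine genes rose (7), Ccl2 going from 38.1 ± 7.97 to 757 ± 84.6 CPM (SD, n = 3 each). Of 11 glycolysis and hypoxia genes 6 rose (6), with Pkm at 0.86 ± 0.13, and 6 of 15 oxidative phosphorylation genes (6), with Ndufa1 at 0.66 ± 0.090 and Cox5a at 0.68 ± 0.11. The set test gave an adjusted p of 0.181 with an estimated correlation for the first 4 of these lists, 0.282 for glycolysis and 0.412 for oxidative phosphorylation.

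In ependymal cells 11 of 15 MHC class I genes rose (15 adjusted over the list alone), H2-K1 from 159 ± 38.3 to 1648 ± 233 CPM, and 12 of 15 type I interferon genes (15), Ifitm3 from 758 ± 160.0 to 3124 ± 519.8, each with an adjusted p of 0.0694 with an estimated correlation. A list fixed for stressed oligodendrocytes, whose members H2-K1 and H2-D1 present antigen and are in the class I list too, rose in 7 of 8 (8 adjusted over the list alone), and its adjusted p was 0.0215 with an estimated correlation. Cd74 is a member as well. Lyz2, Ccl5, Cd74 and Tyrobp stood at 281, 69.9, 792 and 190 CPM in EAE ependymal cells against 44.5, 6.57, 69.7 and 102 in CTL. In fibroblasts 4 of 11 chemokine and cytokine genes rose (6), with an adjusted p of 0.0955 with an estimated correlation. Among them Ccl5 rose by 2.63 ± 0.40, beside the leukocyte transcripts Lyz2 at 198 CPM in EAE against 54.1 in CTL and Cd74 at 1197 against 339. The myeloid gene Tyrobp stood at 114 against 102 in these fibroblasts. In cells annotated as macrophages 9 of 12 glycolysis and hypoxia genes rose (12), with Ddit4 at 2.26 ± 0.37 and Egln3 at 2.93 ± 0.55, and 10 of 11 genes of resting microglia fell (11), with Fcrls at -4.94 ± 0.25 and P2ry12 at -3.01 ± 0.16. The adjusted p with an estimated correlation was 0.431 and 0.165 for these lists.

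Transcripts of blood and choroid plexus in CD31-positive cells were lower in both libraries of batch 1 than in every library of batch 2. The haemoglobin gene Hbb-bs stood at 129.8 and 1325 CPM in EAE replicates 1 and 2 and at 70.1, 3461 and 1740 in CTL replicates 1, 2 and 3. The choroid plexus gene Ttr stood at 52.4 and 775 in EAE and at 107, 1003 and 3352 in CTL. The first library of each condition was from batch 1 and the others from batch 2. Within batch 2, Hbb-bs was above 0 in 11.7% of the cells of EAE replicate 2 against 73.4% and 60.7% in CTL replicates 2 and 3. In total endothelial cells of batch 2 it stood at 7.83 CPM in EAE replicate 3 against 2133 and 2405 in CTL replicates 2 and 3, and below 1 CPM in each library of batch 1. Of 4 tested erythrocyte genes in total endothelium 0 were called over all genes, and 4 fell adjusted over the list alone, with a median log2 fold change of -2.65.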
